A study of Pinctada fucata with 3 samples.

How the data were processed

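RNA from the mantle of the pearl oyster Pinctada fucata was sequenced after injection of double-stranded RNA (dsRNA), which triggers RNA interference against the matching transcript. The mantle is the tissue that secretes the shell. There were 3 libraries, 1 per treatment: dsRNA against Rel, dsRNA against IκB, and dsRNA against green fluorescent protein (GFP), which is absent from oysters and served as the control. Per the labels' protocols, 30 μg of dsRNA was injected into the adductor muscle, each group held 5 oysters, and a piece of mantle was taken from each oyster 7 days later. Each group is 1 library, which implies a pool of the pieces, though the labels do not state one, so the spread between oysters cannot be seen. The labels' protocols describe both poly(A) capture and removal of ribosomal RNA and do not say which was applied to which library.

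The authors deposited 1 table of FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments), rounded to 2 decimals, with 33072 genes and 3 columns. The submitters' processing notes name HISAT, Bowtie2 and RSEM without versions. Their roles, the genome build and the annotation are not given in the sources used here. Fields in the deposited file are separated by 1 to 3 tabs, and all lines hold 4 fields, which were read in header order. The columns were matched to the libraries by name, and no column was left unused. Of the gene identifiers, 21323 begin with pfu_aug2.0 and 11749 with BGI_novel. The file does not pair identifiers with gene names, and no annotation was used here. The 20 gene lists planned before the data were examined (among them shell matrix proteins, the NF-κB and Toll pathway, immune effectors, and markers of muscle, cilia, haemocytes, neurons and germ line) therefore could not be applied, and the Rel and IκB transcripts were not analysed here, so the knockdown itself was not checked.

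Genes entered the comparisons if their mean over the 3 libraries was at least 1 FPKM, which left 20728 genes. Of these, 828 had the same 3 values as another gene, in 391 sets, and each was counted as a gene. The log2 ratio of FPKM + 1 was computed for each pair of libraries, and genes at or past 2-fold were counted in each direction. The pseudocount of 1 understates the change of genes with low values. With 1 library per group there is no replicate check, no p-value was computed, and edgeR and other count models were not used, since the values are not counts. Fold changes describe these libraries, not the treatments in general. A gene listed at 0 is described as such, with no fold. By the rule fixed for identifiers without names, the 2 with the largest increase and the 2 with the largest decrease are named in each comparison.

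The number of reads per library is unknown from FPKM, so no counting interval or detection floor is given. Relative depth was estimated from the low values (0.3 to below 3 FPKM), where a value is close to a whole multiple of what 1 read is worth. The most frequent ratio between 2 libraries, searched only in a limited range around equal depth, was taken as the ratio of their read worth. A gap in depth beyond that range could not have been found. On simulated whole reads for 33072 genes, this estimate came within a factor of 1.0013 of the true ratio for Rel against GFP dsRNA. For IκB against GFP dsRNA the factor was 1.0017. The simulated true ratios lay inside the searched range, so this checks the estimate only for whole reads and gaps within that range. The counting of changed genes was tested on simulated libraries made from the real mean FPKM values for Rel against GFP dsRNA, with 200 genes changed 4-fold. These 200 genes were drawn only from those with a mean of at least 5 FPKM. All (100%) of the changed genes were recovered without noise and 86% with noise of SD 0.5 (log2) per library. At these means a 4-fold change passes 2-fold despite the pseudocount, so the recovery without noise only checks the code. Recovery at lower means was not tested, and the share of unchanged genes called is not given.

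Both knockdown libraries were compared with the same control library, which gives their log2 ratios a shared part even without any effect. This part was estimated from 100 simulated sets of 3 unchanged libraries, whose spread was drawn from the difference between the knockdown libraries within 40 bins of mean FPKM. All of that difference was treated as noise, and the simulated sets held more genes past 2-fold than the knockdown pair they were drawn from. The number of genes that 2 independent lists of the same sizes would share was computed as well. For 3 libraries, the covariance between the log2 ratios of the other 2 libraries against one of them was taken as the variance across genes that sets that library apart. It does not tell what is peculiar to a library from what the other 2 share.

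The alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, rescaling to a sum of 1000000 per library (the TPM scale), median-ratio scaling, scaling to the 75th percentile, and a 3-fold threshold. A restriction to genes above 0 in all 3 libraries and a count with genes of identical values counted once were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.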

Results

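To examine how NF-κB signalling acts on the mantle of Pinctada fucata, the transcriptomes of oysters injected with dsRNA against Rel, a transcription factor of the NF-κB family, or against IκB, the protein known to hold such factors inactive in the cytoplasm, were set against those of oysters injected with GFP dsRNA. Each treatment was represented by 1 library, from a group of 5 oysters sampled 7 days after 30 μg of dsRNA. That the pieces of the 5 oysters were pooled is implied and not stated. No value has a replicate error, and the differences below are between libraries. The gene identifiers carry no names in the deposited file, so groups of genes are described by their level and their direction of change.

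All 3 libraries covered most of the listed genes and were dominated by a small set of abundant transcripts. Of 33072 genes, 27249 were above 0 in the GFP dsRNA library, 28783 in the Rel dsRNA library and 29005 in the IκB dsRNA library. The 100 most abundant genes of each library held 53.4% of all FPKM in the GFP dsRNA library, 49.3% in the Rel dsRNA library and 54.3% in the IκB dsRNA library, and the highest single values were 26938, 17386 and 22500 FPKM. Genes at 100 FPKM or more numbered 1009, 964 and 968 in the same order. FPKM summed to 1166698, 1006661 and 1126540. Judged from the steps between low values, the Rel and IκB dsRNA libraries were 1.18 and 1.16 times as deep as the GFP dsRNA library, and the number of reads behind them is unknown.

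With Rel dsRNA, 38.6% of the 20728 genes with a mean of at least 1 FPKM differed at least 2-fold from GFP dsRNA. Of these, 4249 genes were higher and 3747 were lower, or 4756 and 2937 on the TPM scale, and the balance turned to 2048 higher and 2139 lower among genes with a mean of at least 5 FPKM. Unchanged libraries were simulated with spread drawn from the difference between the knockdown libraries. They held 4094.9 genes at least 2-fold apart on average (3958 to 4204), against the 7996 observed. The knockdown libraries themselves had 3547 such genes, fewer than any simulated set, so the simulated counts run high for that pair. At least 4-fold differences were seen for 1568 genes that were higher and 1199 that were lower, and at least 16-fold differences for 192 and 83. Genes with pfu_aug2.0 identifiers (2094 higher and 1692 lower of 10148) and with BGI_novel identifiers (2155 higher and 2055 lower of 10580) were both represented in each direction. Among the 100 genes with the highest mean FPKM, 11 were at least 2-fold higher and 23 at least 2-fold lower with Rel dsRNA. These 100 genes made up 47.3% of all FPKM with Rel dsRNA and 50.3% with GFP dsRNA. The largest increases were those of BGI_novel_G010857, listed at 0 with GFP dsRNA and at 577 FPKM with Rel dsRNA, and of BGI_novel_G003041, listed at 0 and at 463 FPKM. The largest decreases were those of BGI_novel_G003267, at 1530 FPKM with GFP dsRNA and listed at 0 with Rel dsRNA, and of pfu_aug2.0_3201.1_05782, at 298 FPKM and listed at 0. In the IκB dsRNA library these genes stood at 218, 21.0, 501 and 33.8 FPKM, between the values of the other 2 libraries. The median log2 ratio of all tested genes was 0.01.

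With IκB dsRNA, 37.1% of the same genes differed at least 2-fold from GFP dsRNA, 3941 of them higher and 3752 lower. This balance turned to 1901 and 2119 among genes with a mean of at least 5 FPKM, and to 3026 and 3190 among genes above 0 in all 3 libraries. The 4-fold mark was passed by 1575 higher and 1103 lower genes and the 16-fold mark by 170 and 66. Among the 100 genes with the highest mean FPKM, 12 were at least 2-fold higher and 15 at least 2-fold lower, and these genes made up 53.4% of all FPKM with IκB dsRNA. At a pseudocount of 1 the largest increase was that of BGI_novel_G008730, from 4.09 FPKM with GFP dsRNA to 2988 FPKM with IκB dsRNA, a log2 ratio of 9.20 on the FPKM + 1 scale. BGI_novel_G005202 was second, listed at 0 with GFP dsRNA and at 239.8 FPKM with IκB dsRNA, and it ranked above BGI_novel_G008730 at a pseudocount of 0.1. The largest decreases were those of BGI_novel_G008728, at 1435 FPKM with GFP dsRNA and listed at 0 with IκB dsRNA, and of BGI_novel_G010214, at 387 FPKM and listed at 0. The ID numbers of BGI_novel_G008728 and BGI_novel_G008730 lie within 3 of each other, and these genes changed in opposite directions. Reads assigned to a near-identical copy with a neighbouring ID were not excluded, so the pair may not hold separate responses. With Rel dsRNA, BGI_novel_G008730 was at 14.4 FPKM, BGI_novel_G005202 at 95.9 FPKM, BGI_novel_G008728 at 290.4 FPKM and BGI_novel_G010214 at 87.3 FPKM. The median log2 ratio of all tested genes was -0.03.

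Rel and IκB are known to act in opposite directions on NF-κB target genes, so the knockdowns were compared with each other for genes that moved together or apart. Of the tested genes, 2902 were at least 2-fold higher with both dsRNAs and 2514 at least 2-fold lower with both, against 807.9 and 678.2 for independent lists of the same sizes. The genes higher with both had a median of 0.97 FPKM with GFP dsRNA, 7.96 FPKM with Rel dsRNA and 7.50 FPKM with IκB dsRNA. The genes lower with both had medians of 14.9, 3.26 and 3.41 FPKM in the same order. Opposite changes were fewer: 35 genes were at least 2-fold higher with Rel dsRNA and at least 2-fold lower with IκB dsRNA, and 38 genes showed the reverse, against 769.1 and 712.4 for independent lists, which leave out the shared control. These counts were 128 and 119 at a pseudocount of 0.1, and 15 and 18 among genes above 0 in all 3 libraries. Among the 100 genes with the highest mean FPKM, 7 were higher with both, 15 were lower with both, and 0 moved apart past 2-fold.

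**Figure D1:**
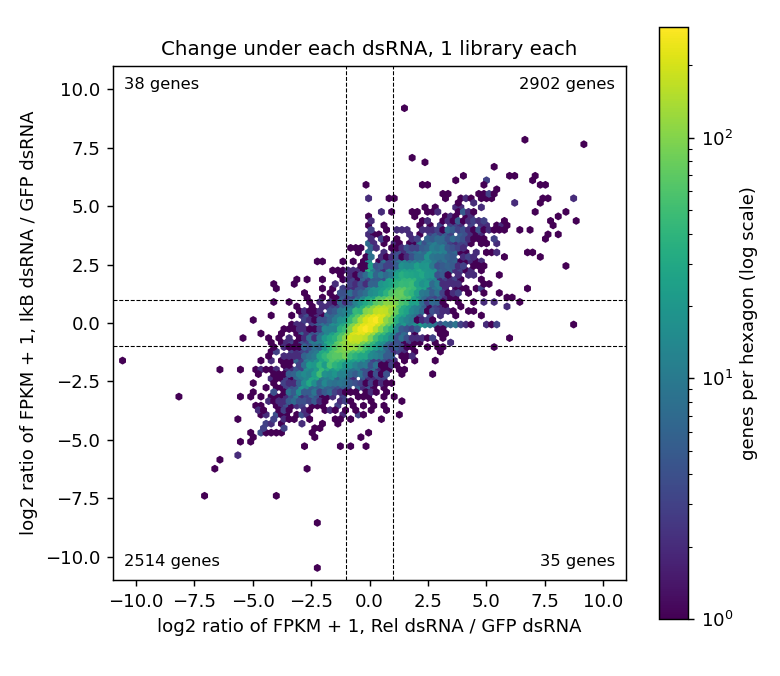
Each hexagon counts genes (color, log scale) by their log2 ratio of FPKM + 1 with Rel dsRNA (x axis) and with IκB dsRNA (y axis) against the same GFP dsRNA library, for 20728 genes and 1 library per treatment; dashed lines mark 2-fold. Most genes lie along the diagonal, with 2902 past 2-fold at the upper right and 2514 at the lower left, and 38 and 35 in the other corners.

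Because the GFP dsRNA library enters both ratios, part of this likeness arises without any effect. Across genes, which are not independent replicates, the log2 ratios with Rel and with IκB dsRNA correlated at r = 0.79, against a mean of 0.50 in 100 simulated sets of unchanged libraries sharing 1 control. The observed covariance was 1.45 and the simulated covariance averaged 0.40 (highest 0.41), a difference of 1.06. The simulated sets held 1587 genes past 2-fold in the same direction on average, and at most 1679, against 5416 observed. They held 100.2 genes past 2-fold in opposite directions on average (76 to 123), against 73 observed at a pseudocount of 1, below that range. The simulated spread comes from the difference between the knockdown libraries, which would hold any opposite effects. The comparison therefore cannot tell whether the 73 exceed what unchanged libraries give. With a single control library the shared part could not be split from the control, and part or all of the excess may come from that library. The variance across genes that set each library apart from the other 2 was 1.45 for GFP dsRNA (64.7% of the sum), 0.46 for Rel dsRNA and 0.33 for IκB dsRNA. The value for GFP dsRNA is the same covariance, so it also holds any response shared by both dsRNAs. Among the 6430 genes with a mean of 10 FPKM or more its share was 73.9%.

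In the direct comparison, whose log2 ratios do not use the control, 17.1% of the tested genes differed at least 2-fold between IκB and Rel dsRNA. Of the genes that differed, 1665 were higher and 1882 lower with IκB dsRNA. The balance between the directions depended on the scaling: 46.9% of these genes were higher in the deposited scale, 36.6% on the TPM scale (1280 higher and 2221 lower), 52.1% with median-ratio scaling (1840 and 1689) and 50.03% with upper-quartile scaling (1795 and 1793). The control still entered the choice of tested genes, by the mean over the 3 libraries, and the median-ratio and upper-quartile scalings. Genes at least 4-fold apart numbered 479 higher and 469 lower with IκB dsRNA. The log2 values of the knockdown libraries correlated across genes at r = 0.89, compared with 0.75 between Rel and GFP dsRNA and 0.77 between IκB and GFP dsRNA. Of the 5416 genes that moved alike against GFP dsRNA, 780 (14.4%) were also at least 2-fold apart between the knockdowns. Another 496 genes were at least 2-fold apart between the knockdowns without passing 2-fold against GFP dsRNA in either. At a pseudocount of 1 the genes furthest above Rel dsRNA in the IκB dsRNA library were BGI_novel_G003267 (501 FPKM, and listed at 0 with Rel dsRNA) and BGI_novel_G008730 (2988 against 14.4 FPKM). The genes furthest below were pfu_aug2.0_352.1_07393, at 455 FPKM with Rel dsRNA and listed at 0 with both other dsRNAs, and BGI_novel_G008728, at 290.4 FPKM with Rel dsRNA and listed at 0 with IκB dsRNA. BGI_novel_G008730 and BGI_novel_G008728 are the neighbouring pair named above.

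The differences from GFP dsRNA were found among rare and abundant transcripts. Of the 4285 genes with a mean of 1 to 2 FPKM, 34.0% differed at least 2-fold with Rel dsRNA, 34.0% with IκB dsRNA, and 20.2% between the knockdowns. Of the 577 genes with a mean of 200 FPKM or more, 151 were higher and 143 lower with Rel dsRNA (51.0% in all). In the same group 147 were higher and 116 lower with IκB dsRNA (45.6%), and 38 were higher and 47 lower with IκB than with Rel dsRNA (14.7%). The pseudocount of 1 lowers the share among the rarest genes: with 0.1 FPKM in its place, 37.1% of the genes at 1 to 2 FPKM and 38.6% of those at 50 FPKM or more moved alike with both dsRNAs, compared with 19.4% and 38.2%. The share at least 2-fold apart between the knockdowns was then 38.0% at 1 to 2 FPKM and 14.8% at 50 FPKM or more.

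**Figure D2:**
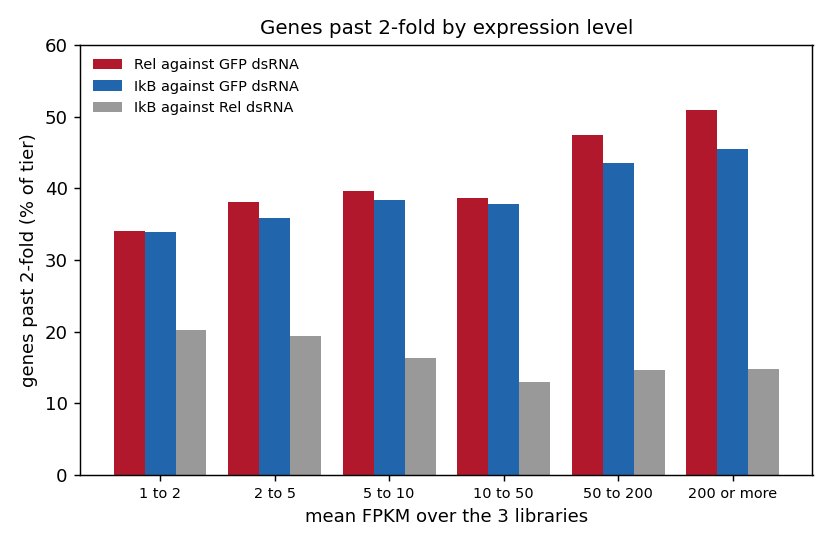
Bars give the percentage of genes past 2-fold (y axis) in 6 tiers of mean FPKM over the 3 libraries (x axis), for Rel against GFP dsRNA (red), IκB against GFP dsRNA (blue) and IκB against Rel dsRNA (grey), with 1 library per treatment and no error bars. At 200 FPKM or more the bars reach 51.0%, 45.6% and 14.7%.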

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

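No p-value was computed, so there was no call to lose, and no replicate could be left out. The scaling alternatives and dropping the filter moved no count past 1.5 times and turned no direction among the named genes, but the balance of higher and lower genes for IκB against Rel dsRNA turned with the scaling. For both dsRNAs against GFP dsRNA it turned with a mean of at least 5 FPKM, and for IκB dsRNA also among genes above 0 in all 3 libraries (3026 and 3190). The TPM scale moved the median log2 ratio by 0.17 for Rel against GFP dsRNA and by -0.13 for IκB against Rel dsRNA. With a pseudocount of 0.1 the opposite changes were 128 genes higher with Rel and lower with IκB dsRNA and 119 the reverse, and 6956 genes moved alike, 5416 of them those of the pseudocount of 1. The log2 ratios of the named genes listed at 0 in a library compared, 10 values, moved by over 1.5-fold. BGI_novel_G005202, listed at 0 with GFP dsRNA, then ranked above BGI_novel_G008730 (9.48). Its own value (11.23, and 7.91 at a pseudocount of 1) depends on the pseudocount and is not a measured fold. With a mean of at least 5 FPKM, fewer genes were tested: 2048 were higher and 2139 lower with Rel dsRNA, 1901 and 2119 with IκB dsRNA, and 706 and 780 for IκB against Rel dsRNA, with 1582 higher and 1546 lower in both and 17 and 16 opposite. A 3-fold threshold gave 2398 and 1934, 2313 and 1813, and 721 and 753 in the same order, with 1466 and 1144 in both and 2 and 8 opposite. Among genes above 0 in all 3 libraries, a restriction added after the data were seen, 15 and 18 were opposite, so the rest of the 73 opposite changes involved a value of 0. Counting genes of identical values once, also added after, removed 437 genes and gave 4164 higher and 3668 lower with Rel dsRNA. In all, 66 of the counts stayed within 1.5 times and 24 did not. The alternatives planned for the gene lists and the targeted genes were not run, since the deposited file names no identifier and no annotation was used. Depth in reads is unknown, so a gene listed at 0 is not shown to be absent.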

Other observations

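The tests of depth and scaling for the control library as a whole, the weighing of the single control, and the ceiling on the zeros that depth can give were chosen after the results were seen. Some abundant transcripts of one library were listed at 0 in another. Of the genes at 50 FPKM or more in at least 1 library, 30 were listed at 0 in another: 22 with GFP dsRNA, 6 with Rel dsRNA and 3 with IκB dsRNA, 1 of them in 2 libraries. At 10 FPKM or more in at least 1 other library, 196 genes were listed at 0 with GFP dsRNA, 103 with Rel dsRNA and 103 with IκB dsRNA. By a stricter rule, 24 genes reached 10 FPKM with GFP dsRNA while listed at 0 in both other libraries. The same rule gave 27 genes with Rel dsRNA and 15 with IκB dsRNA. These counts are not the mirror of those before, which needed 10 FPKM in only 1 other library.

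Both knockdown libraries lay on the same side of the GFP dsRNA library for most changed genes, although the targets are known to oppose each other. A lower depth of the control library was argued against as the whole cause by 38.2% of the genes at 50 FPKM or more moving alike. This share was not lower than the 19.4% at 1 to 2 FPKM. Most of that gap came from the pseudocount and not from depth: with 0.1 the shares were 38.6% and 37.1%. Composition or scaling that puts 1 factor on the control library was argued against as the whole cause: over factors from 2-fold down to 2-fold up, the number of genes that moved alike fell no lower than 5175, against 5416 in the deposited scale and at most 1679 in simulated unchanged libraries. It was 4994 on the TPM scale, which rescales all 3 libraries. A spread of the control library no larger than that between the knockdown libraries was argued against as the whole cause. The covariance was 1.4542, above the highest simulated value of 0.4132. It also holds any response shared by both dsRNAs, so such a spread together with a shared response stays open. A response shared by both dsRNAs and a control library that differed in its oysters, mantle pieces or RNA preparation (poly(A) capture and removal of ribosomal RNA are both described) cannot be told apart with 1 control library.

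For the 30 genes at 50 FPKM or more in 1 library and listed at 0 in another, 71.0% of the zeros were in the control library, the shallowest by the steps of its low values. A share over 50% had been set in advance as the mark of a lower depth of the library with the 0, and it was met, but that mark was too lenient for knockdown libraries only 1.18 and 1.16 times as deep. With Poisson reads, this gap puts at most 47.4% of the zeros in the control library when matched to its 22 zeros (11.7 and 12.7 zeros with Rel and IκB dsRNA, where 6 and 3 were seen), below the exact 95% interval of the observed share (52.0% to 85.8%). This argues against depth as the whole cause only if the estimate of depth holds, reads are Poisson and the zeros are independent. The ceiling was chosen after the results were seen. Reads assigned to a near-identical copy with a neighbouring ID would leave a neighbour with the opposite change. Of these genes, 50% had one within 3 ID numbers, and 95% of 10000 random sets matched on FPKM lay between 26.7% and 60%. For random genes, a neighbour counted if it rose at least 2-fold between the same libraries, whatever the random gene itself did. That range is therefore not a rate of opposite changes, and the test cannot tell whether reads were so assigned. BGI_novel_G008728 was among the 30 genes, with BGI_novel_G008730 as an opposite neighbour. Copies elsewhere in the genome were not searched, and gene content that differs between oysters was not tested.

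Against GFP dsRNA, genes with consecutive ID numbers changed slightly more alike than shuffled genes. The pfu_aug2.0 identifiers appear to run in order within their middle field. They form 6863 groups by that field, 3309 of them with 2 or more IDs, with 0 overlapping number ranges. Within these groups the log2 ratios of Rel against GFP dsRNA correlated at 0.148 across 2980 pairs of neighbours, above the highest of 100 shuffles (0.0578). For this comparison a shared level of expression was argued against as the whole cause, since ranks among genes of like FPKM still correlated at 0.1026 (highest shuffle 0.041). At a distance of 5 the correlation was 0.0060, within the shuffles (highest 0.0572). A transcript split over several IDs would give this, but so would any other cause of short range, so the test does not single it out. Short clusters of genes that change together were not tested. For BGI_novel identifiers the correlation between neighbours was 0.138 for Rel and for IκB (0.1375) against GFP dsRNA, and 0.0010 for IκB against Rel dsRNA (highest shuffle 0.0208). For pfu_aug2.0 identifiers the direct comparison gave 0.0682, above its highest shuffle of 0.0398, but its ranks gave 0.0417, within the shuffles (highest 0.0427), so there a shared level of expression stays open. Some neighbours had identical values in all 3 libraries, as 1 sequence listed under 2 IDs would: 325 of the 9130 BGI_novel pairs and 1 of the 2980 pfu_aug2.0 pairs. Identical values were argued against as the whole cause, since the other BGI_novel neighbours still correlated at 0.1154 for Rel against GFP dsRNA (highest shuffle 0.0263) and at 0.1161 for IκB against GFP dsRNA (highest shuffle 0.0201). For IκB against Rel dsRNA they did not change alike: their correlation was -0.025, just below the lowest shuffle (shuffles from -0.0241 to 0.0294).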
